A study of Mus musculus with 12 samples.

How the data were processed

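Gene expression was measured on 12 Affymetrix microarrays, 1 for each sample of liver sinusoidal endothelial cells (LSEC) from mice. Per the labels' protocols, each sample pooled livers of 3 mice that were perfused and digested with collagenase, the digestion lasting 25 min at 38 °C. Nonparenchymal cells were then taken from a 19.3% Nycodenz density gradient, and LSEC were selected magnetically with beads against CD146, the product of Mcam. Total RNA was converted to biotin-labelled cRNA for hybridization. The labels place 6 samples in a control group and 6 in a group from mice carrying Clec4g-Cre and a Rosa26 allele of the Notch1 intracellular domain with a GFP reporter, called NICD_OE here. They name the samples of each group as biological replicates, and the full genotype of the control mice is not given in the sources used here.

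The deposited values are log2 expression values, 1 per probe set and array, and the authors made them with RMA (background correction, quantile normalization and probe set summary), per the submitters' processing notes. The software that ran RMA, the chip definition and the genome build are not given in the sources used here, so no coordinates are reported. The values carried no detection calls, so a low log2 value, taken here as one below the array median, cannot be separated from background. Every array had a median of 3.67 and a maximum of 13.4, and the quantiles were the same on all arrays except for a minute offset on control replicate 1 (median 3.674581 against 3.674316). Because the arrays share their quantiles, a change that moved most genes one way would not show in these values.

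Of 25428 probe sets, 24705 had 1 gene symbol in the platform annotation, dated 2018, 0 had several and 723 had none. Entrez identifiers of 24673 named probe sets were found in a RefSeq gene table of GRCm38.p6, used only for names, and 0 of their symbols differed from it. 1 symbol had 2 probe sets and was represented by the brighter. No probe set was filtered out for the counts given in the report.

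Differences were computed as NICD_OE minus control on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, 2 groups, no covariates). All p-values are two-sided. P-values were adjusted by the Benjamini-Hochberg method over all probe sets, and an adjusted p under 0.05 counted as a call. SE is limma's moderated standard error, and SD is the spread between the 6 arrays of a group. The arrays' number, 6 per group, limits the precision.

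Gene lists were tested with limma's camera at the preset correlation of 0.01, adjusted over 38 lists, of which 26 covered pathways and endothelial states and 12 held markers of other cell types. Counts of members are given over all genes and, for these 38 lists, adjusted over the list alone. Camera with the correlation estimated from the arrays, and fry, which tests whether a list's genes move one way on balance, were run as alternatives. The mean over each list's genes was also compared by a two-sided exact permutation test over the 924 ways to assign 6 of the 12 arrays, whose smallest possible p is 0.002165. Lists share members (Jag1, Dll4 and Efnb2 stand in several), so their tests are not independent.

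The lists, the test, the processing alternatives and the rule for naming genes were fixed before the data were examined. The rule names 28 preselected genes. It adds the 10 genes with the largest positive and the 10 with the largest negative difference among called genes whose groups did not overlap, leaving out predicted genes named Gm, Rik or LOC. In each list it names up to 4 called members by size, or the 2 largest differences where none was called. Further list members are named in the text to complete small counts or the account of a group, and those were chosen after their values were seen.

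Alternatives comprised median centring of each array, a further quantile normalization, leaving out the dimmest 25 or 50 percent of probe sets, an intensity trend with robust eBayes, array weights, the replicate number as a block, each array left out in turn, an absolute log2 difference of at least 1, the mean of all probe sets of a gene, and the other list tests. Chosen after seeing the data were a fit without 2 arrays that stood apart and fits with a marker mean (hepatocyte, neutrophil or early-response genes) as a covariate, and lists without the Notch target genes they hold.

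The limma and camera steps were tested on simulated data built from these 25428 probe sets for NICD_OE against control. Of probe sets changed by log2 0.5, 54.5% of 55 were recovered, against 94.2% of 69 at log2 1 and 100% of 76 at log2 2. Of 181 calls in that simulation, 5.52% were of unchanged probe sets. A list moved by log2 0.5 was called and 0 of 31 unmoved lists were. Each probe set was drawn independently there, whereas members of the real lists had estimated correlations of up to 0.815. The simulation therefore does not show how often unmoved lists of correlated genes pass at the preset correlation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.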

Results

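Liver sinusoidal endothelial cells line the fenestrated capillaries of the liver, clear waste from the blood and supply growth factors to hepatocytes. Their expression was compared between 6 control samples and 6 samples from mice whose hepatic endothelium overexpressed the Notch1 intracellular domain (NICD_OE), the fragment of the receptor that enters the nucleus and activates transcription. The comparison asks which genes differ when Notch signalling is switched on in these cells. Each sample was a pool from 3 mice on its own array, with 25428 probe sets and log2 RMA values. Correlations between arrays of a group ran from 0.976 to 0.992, and no array duplicated another.

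The groups separated along the first principal component, which held 35.4% of the variance, with controls from -34.6 to -22.2 and NICD_OE arrays from 20.9 to 36.6. The second component held 16.4% and set control 2 (-48.5) and NICD_OE 4 (-30.3) apart from the other arrays, which lay between -8.51 and 22.3. Without these 2 arrays, a fit chosen after seeing the data, 1289 probe sets were higher and 1481 lower.

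**Figure D1:**
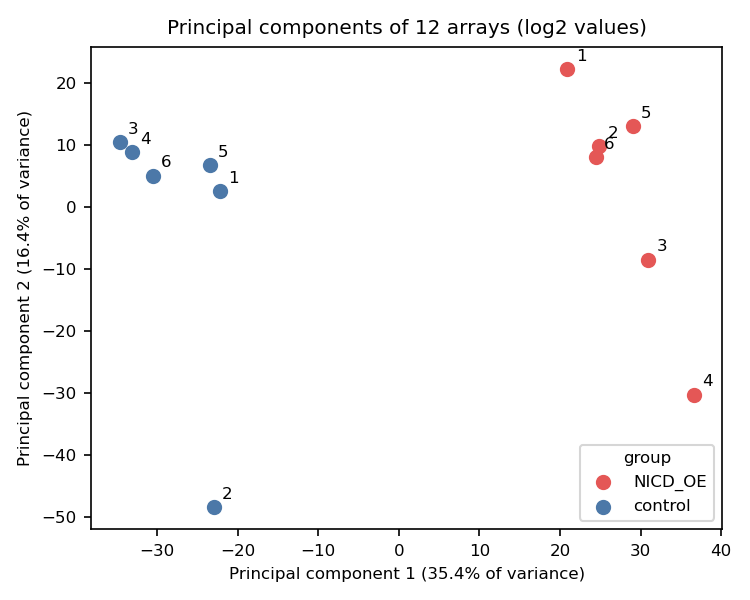
Scores of the 12 arrays on the first principal component (x axis, 35.4% of variance) and the second (y axis, 16.4% of variance), computed from log2 values; each point is 1 array, coloured by group and numbered by replicate. All 6 control arrays lie left of 0 and all 6 NICD_OE arrays right of it, with control 2 and NICD_OE 4 lowest on the y axis.

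NICD_OE cells carried a broad change that ran in both directions. Of the 25428 probe sets, 1244 were higher and 1422 lower in NICD_OE at an adjusted p under 0.05, together 10.5%. With a log2 difference of at least 1 as well, 330 were higher and 201 lower. The groups did not overlap for 1698 probe sets, 6.68% against the 0.216% that chance gives. The median difference of all probe sets was -0.01. Because the arrays share their quantiles, neither this median nor the balance of directions can show whether most genes moved one way. For 15 of the 122 named genes that were called, the mean of the lower group lay below the array median of 3.67, where a level cannot be separated from background, so the sizes of their differences are not exact and do not rank them. They are Heyl, H19, Mcemp1, Stc1, Fgf23, Il13ra2, Olfr1396, Ces2e, Cxcl2, Dkk2, Egln3, Angptl4, Cd209a, Retnlg and Krt19. Among 38 gene lists, 26 passed the threshold at the preset correlation (23 higher, 3 lower) and 11 held with an estimated correlation (9 higher, 2 lower). Those 11 are Notch targets, sinusoidal identity, continuous capillary, basement membrane, arterial, pericentral, periportal, adhesion, hypoxia and glycolysis, fatty acid handling and cholangiocyte markers.

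Listed Notch target genes rose as a group, and whether Notch acts on them directly was not measured. Hey1, a transcriptional repressor induced by Notch in arteries, rose from 4.42 ± 0.38 to 7.11 ± 0.23 (SD, n = 6 each), 6.48-fold on the linear scale (log2 difference 2.70, SE 0.16, adjusted p = 4.15e-08). Nrarp, a feedback inhibitor of Notch, rose by 1.04 (SE 0.12, adjusted p = 2.23e-05). Hes1, a repressor of the same family as Hey1, rose by 0.76 (SE 0.13) and Heyl by 0.50 (SE 0.13). Heyl ranged from 0.44 to 0.59 over single arrays left out and lost its call without control 3, 4 or 5 or NICD_OE 2, 4 or 6. Jag1 and Dll4, ligands of Notch, rose by 1.54 and 0.90, and Myc, a growth regulator, by 1.73. Myc ranked the NICD_OE arrays, from 6.50 on NICD_OE 1 to 8.16 on NICD_OE 5, as did the mean of early-response genes, which cell isolation can induce. In control it did not, and the source of the Myc rise was not tested. Hey2 differed by 0.28 and was not called (adjusted p = 0.137). Of 17 measured target genes 9 rose and 1 fell (10 and 2 adjusted over the list alone), with a median of 0.50 and an adjusted p of 4.05e-07 (0.00364 with an estimated correlation). Lfng, a glycosyltransferase that modifies Notch receptors, was the one that fell (-1.37).

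The receptor gene itself gave no call. Notch1 was 8.68 ± 0.26 in control and 8.87 ± 0.24 in NICD_OE (SD, n = 6 each; log2 difference 0.19, SE 0.14, adjusted p = 0.486). Whether its probe set covers the part of the gene carried by the transgene is not known here, so this value does not check the labels. Clec4g, the gene whose regulatory sequence drives the Cre, fell from 12.34 to 11.53 (log2 difference -0.81, SE 0.10, adjusted p = 7.61e-05). Among 27 measured receptors, ligands and processing genes 4 rose and 6 fell (6 and 6 adjusted over the list alone), and the list did not pass (adjusted p = 0.896). The fallers included Numb, an inhibitor of Notch (-0.79), and Rbpj, the DNA-binding partner of the intracellular domain (-0.46).

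Genes that mark sinusoidal endothelium fell as a group. Of 25 measured, 19 fell and 2 rose (21 and 2 adjusted over the list alone), with a median of -0.63 and an adjusted p of 1.15e-16 (0.0256 with an estimated correlation). Gata4, the transcription factor that specifies this endothelium, fell by 0.65 (SE 0.09, adjusted p = 1.18e-04), and Maf, another of its regulators, fell by 0.78. The hyaluronan and waste scavenger Stab2 fell 2.49-fold from a control level of 11.31 ± 0.12 (log2 difference -1.32, SE 0.10, adjusted p = 3.59e-07). Its relative Stab1 fell by 0.59, with control 2 below the other controls at 10.50. Plxnc1, a semaphorin receptor, fell by 2.64, the endocytic recycling factor Ehd3 by -1.34, and Bmp2, a regulator of hepatic iron sensing, from 10.88 ± 0.07 to 9.44 ± 0.15. The exceptions were Lyve1, a hyaluronan receptor (0.83, adjusted p = 5.45e-05), and Cd36, a fatty acid translocase (0.51, adjusted p = 0.00270), which rose.

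Scavenger and endocytic receptors overlapped with that list. Here 10 of 19 fell and 3 rose (10 and 4 adjusted over the list alone; median -0.54, adjusted p = 2.38e-04). That call was lost with an estimated correlation (adjusted p = 0.108 with an estimated correlation). The lectin Cd209b (-1.72) and the neonatal Fc receptor Fcgrt (-1.28) fell, while Marco, a receptor that is also a macrophage marker, rose by 1.49.

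Continuous capillary genes moved the other way. Cd34, a sialomucin of continuous endothelium, rose from 6.26 ± 0.14 to 8.05 ± 0.19, 3.44-fold (adjusted p = 2.87e-08). Esm1, a proteoglycan of sprouting endothelial tips, had the largest log2 difference measured among the named genes, rising from 6.44 ± 0.36 to 11.55 ± 0.15, 34.6-fold (log2 difference 5.11, SE 0.15, adjusted p = 1.62e-11). Angpt2, a ligand of the Tie2 receptor, rose by 2.84 and Igfbp3 by 3.50. In the list of 19, 12 rose and 2 fell (13 and 2 adjusted over the list alone), with a median of 0.92 and an adjusted p of 2.04e-11 (0.00364 with an estimated correlation). The tight junction gene Cldn5 (-1.24) and Cd300lg (-0.80) fell. Emcn, an endothelial sialomucin, differed by 0.15 and was not called (adjusted p = 0.573). The selection antigen Mcam rose by 0.92, whereas the pan-endothelial genes Cdh5 and Tie1 differed by 0.01 and 0.00.

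Matrix genes rose as well. Of 21 basement membrane and matrix genes 14 rose and 0 fell (16 and 1 adjusted over the list alone), with a median of 0.61 and an adjusted p of 9.63e-15 (0.00975 with an estimated correlation). Mgp, an inhibitor of calcification and BMP, rose by 2.58, fibronectin (Fn1) by 2.25, periostin (Postn) by 2.03 and thrombospondin (Thbs1) by 1.71. Of 15 stellate cell and fibroblast genes on the same arrays 4 rose, among them the collagens Col1a1 (2.49), Col3a1 (2.11) and Col1a2 (1.71), while 2 fell, and that list's call was lost at adjusted p = 0.609 with an estimated correlation. In a mural cell list chosen after seeing the data 7 of 14 rose and 0 fell, lost at adjusted p = 0.0573 with an estimated correlation.

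Arterial genes rose and the venous list showed no common direction. Vegfc, a ligand of VEGF receptors, rose from 6.31 ± 0.23 to 9.53 ± 0.18, and the chemokine receptor Cxcr4 from 5.16 ± 0.36 to 8.06 ± 0.27 (SD, n = 6 each). Of the list, 5 genes (Hey1, Hey2, Dll4, Jag1 and Efnb2) are also Notch targets. Efnb2, the arterial ephrin, rose by 0.99 (SE 0.11, adjusted p = 2.00e-05). Across 22 arterial genes 16 rose and 2 fell (17 and 2 adjusted over the list alone), with a median of 0.94 and an adjusted p of 6.09e-17 (0.00951 with an estimated correlation). The 2 that fell were the connexin Gja4 (-0.60) and the VEGF co-receptor Nrp1 (-0.68). Of 14 venous genes 4 rose and 5 fell (5 and 5 adjusted over the list alone; adjusted p = 0.691). The prostaglandin transporter Slco2a1 fell by 2.27, and von Willebrand factor (Vwf), the peptidase Cpe and the adhesion receptor Vcam1 rose by 1.76, 1.47 and 1.19.

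Landmarks of the zones of the liver lobule moved in opposite directions. Near the central vein, endothelial Wnt2, a Wnt ligand that sustains hepatocyte zonation and growth, fell 9.71-fold from 8.55 ± 0.17 to 5.27 ± 0.51 (SD, n = 6 each; adjusted p = 3.36e-08). The stem cell factor receptor Kit fell from 9.53 ± 0.15 to 6.90 ± 0.14, 6.21-fold (adjusted p = 1.87e-10). Rspo3, an enhancer of Wnt signalling, fell by 1.12 (SE 0.19, adjusted p = 0.00118), Wnt9b by -0.68 (SE 0.19, adjusted p = 0.0339) and the lectin Lgals1 by -1.51. Of 11 pericentral landmarks 7 fell and 2 rose (8 and 2 adjusted over the list alone), with a median of -0.77 and an adjusted p of 6.90e-06 (0.0345 with an estimated correlation). The 2 that rose were the fatty acid binding protein Fabp4 (from 10.73 to 11.94) and P-selectin (Selp, 0.64). Among 11 periportal landmarks 9 rose and 0 fell (9 and 0 adjusted over the list alone; median 0.99, adjusted p = 2.08e-14, or 0.00951 with an estimated correlation). The adhesion receptor Adgrg6 (2.18) and the connexin Gja5 (2.03) led them, and 3 of the landmarks (Dll4, Jag1 and Efnb2) are Notch targets. These 3, Gja5, Ltbp4, Sox17 and Clu also stand in the arterial list, so the periportal and arterial rises are not separate results. Wnt9b lost its call when control 1, 5 or 6 or NICD_OE 4, 5 or 6 was left out, its difference ranging from -0.79 to -0.56 over single arrays left out.

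**Figure D2:**
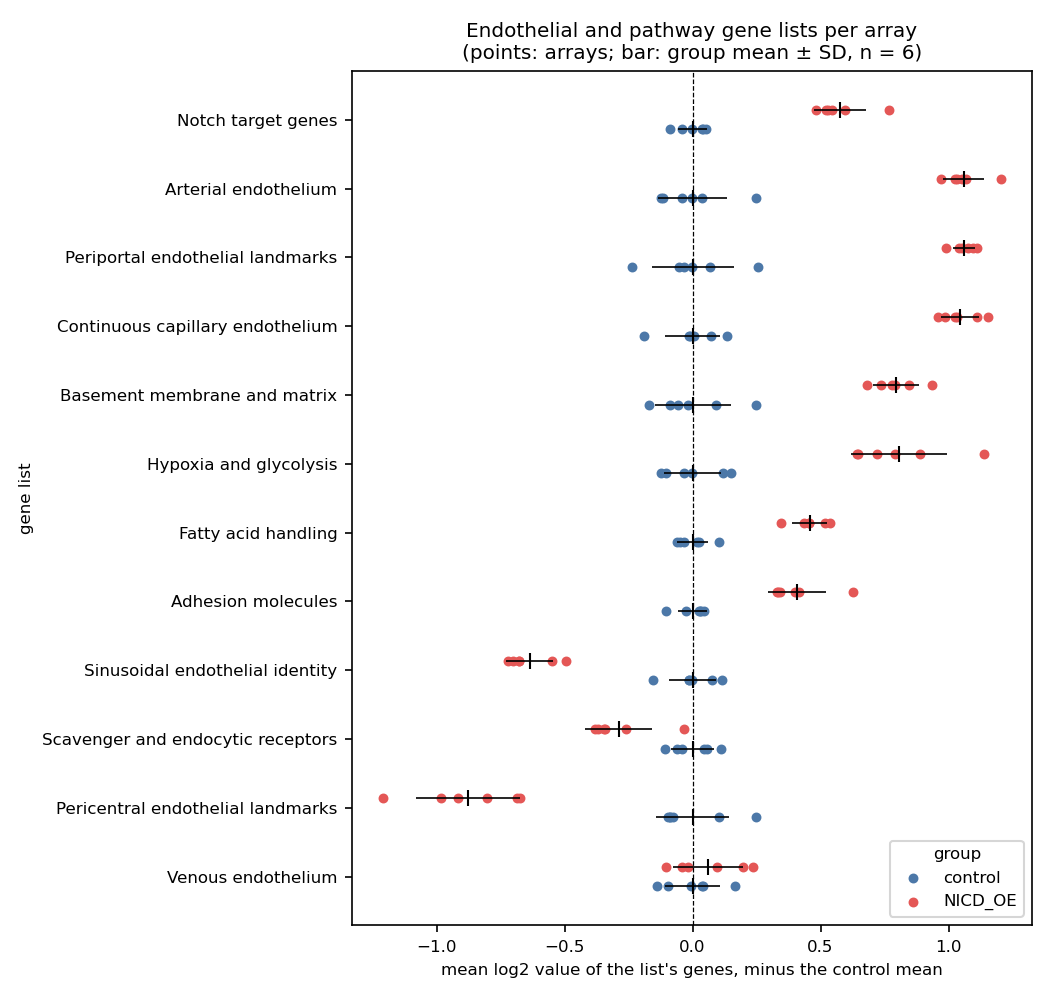
Mean log2 value over the genes of each list, minus the control mean (x axis), for 12 lists (y axis); points are arrays, and bars show the group mean ± SD with n = 6. The NICD_OE arrays lie right of every control array for the Notch target, arterial, periportal, capillary, matrix, hypoxia, fatty acid and adhesion lists and left of every control array for the sinusoidal and pericentral lists.

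Endothelial growth factors split by gene. Hgf, the hepatocyte growth factor, fell from 8.18 ± 0.41 to 6.32 ± 0.50, 3.62-fold (adjusted p = 4.98e-05), with control 1 above the other controls at 8.97, and Ccn2, a matricellular protein, rose by 1.88. Of 23 angiocrine genes 8 rose and 8 fell (8 and 9 adjusted over the list alone), and the list did not pass (adjusted p = 0.580, though 0.00246 with fry), with a median of -9.2e-05 and a mean of 0.14. Among 22 genes of VEGF signalling and sprouting 11 rose and 6 fell (11 and 6 adjusted over the list alone; median 0.23, adjusted p = 1.90e-04), a call that was lost at adjusted p = 0.0999 with an estimated correlation. The fallers there were mainly receptors, Kdr (-0.60), Flt4 (-0.56), Nrp1, Nrp2 (-0.61) and Tek (-0.59), together with the protease Mmp14 (-0.36). In the list of TGF-beta and BMP response 5 of 18 rose and 2 fell (6 and 4 adjusted over the list alone; adjusted p = 0.654, median 0.09, mean -0.01). Bmp2 and Bmp6 (-0.97), 2 ligands, fell, and Bmper (0.60) and Tgfb3 (0.60) rose. Wnt target genes did not pass (adjusted p = 0.654), with 1 of 12 higher, the antagonist Dkk2 (1.82), and 1 lower, the feedback inhibitor Nkd1 (-1.74), and 1 and 1 adjusted over the list alone.

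Hypoxia and glycolysis genes were higher in NICD_OE, on arrays whose early-response genes, which cell isolation can induce, were higher too. The glucose transporter Slc2a1 rose by 2.44, Vegfa by 1.43 and the mitophagy receptor Bnip3 by 0.94. Egln3, an oxygen sensor induced by hypoxia, rose from 3.64, a level not separated from background, to 6.95 (adjusted p = 1.25e-06). Of 17 genes 10 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 0.60 and an adjusted p of 9.87e-13 (0.0256 with an estimated correlation). The early-response mean was higher by 1.29 on the same arrays, and the hypoxia mean went with it. Within NICD_OE Pearson's r was 0.956 (n = 6, exact permutation p = 0.00139, the smallest that 720 orders give) and Spearman's rho 1.00 (exact permutation p = 0.00278), with r at 0.936 without the 2 arrays farthest from the early-response median. Within control r was 0.816 (n = 6, exact permutation p = 0.0278) and rho 0.886 (exact permutation p = 0.0333), with r at 0.643 without the 2 farthest. Of 74 such relations of a list in a group, all chosen after seeing the data, 0 passed adjustment (adjusted p = 0.0514 for r and 0.103 for rho in NICD_OE, 0.283 and 0.352 in control). With the early-response mean as a covariate the list kept its call at the preset correlation (adjusted p = 2.99e-04), and an estimated correlation was not tried there. Slc2a1 (1.76) kept its call too, while Vegfa (0.67, adjusted p = 0.271) and Bnip3 (0.46, adjusted p = 0.641) lost theirs.

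Fatty acid handling genes gave 6 rises and 1 fall among 14 (7 and 2 adjusted over the list alone; median 0.24, adjusted p = 0.00299, or 0.0268 with an estimated correlation). The lipase inhibitor Angptl4 and the nuclear receptor Pparg each rose by 1.85 and Fabp5 by 1.19, while Cpt1a, which admits fatty acids to mitochondria, fell (-0.83).

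Membrane and haemostatic genes shifted less uniformly. In the list of fenestrae and caveolae 6 of 14 rose and 2 fell (7 and 2 adjusted over the list alone; median 0.37, adjusted p = 2.19e-04), lost at adjusted p = 0.0665 with an estimated correlation. The caveolar coat gene Cavin3 rose by 1.85 and the caveolar neck gene Ehd2 by 1.68. Of 20 flow response and haemostasis genes 8 rose and 5 fell (9 and 6 adjusted over the list alone; median 0.18, adjusted p = 0.0211), lost at adjusted p = 0.150 with an estimated correlation, at 0.0508 without NICD_OE 5, at 0.422 with the early-response mean as a covariate and at 0.482 with the neutrophil marker mean. The endothelin receptor Ednrb rose by 2.35, the plasminogen activator Plat by 1.64 and endothelin (Edn1) by 1.62. Mesenchymal transition genes gave 6 rises and 1 fall among 14 (6 and 2 adjusted over the list alone; median 0.12, adjusted p = 8.97e-04), lost at adjusted p = 0.119 with an estimated correlation. Its risers included Fn1, Sox9 (1.12), Tagln (0.94) and vimentin (Vim, 0.82), but the classical transition factor Twist1 fell (-0.53) and Snai1 differed by -0.03 without a call.

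Adhesion molecules rose, and chemokines rose in part. Vcam1, a leukocyte adhesion receptor, rose from 8.34 ± 0.11 to 9.53 ± 0.25 (adjusted p = 4.22e-06) and E-selectin (Sele) by 2.47, while Icam1 differed by 0.53 without a call (SE 0.22, adjusted p = 0.156, range 0.30 to 0.61 over single arrays left out). On NICD_OE 5 Sele (8.33) and Icam1 (9.41) stood above the other NICD_OE arrays. Of 29 adhesion genes 13 rose and 4 fell (16 and 4 adjusted over the list alone; median 0.27, adjusted p = 6.69e-06, or 0.0213 with an estimated correlation). Of 27 chemokines, cytokines and NF-kB targets 8 rose and 1 fell (12 and 3 adjusted over the list alone; median 0.42, adjusted p = 6.35e-05), lost at adjusted p = 0.0999 with an estimated correlation. The neutrophil attractant Cxcl2 rose by 1.88 and the inflammatory cytokine Il1b by 1.18, and Cxcl13, a B cell attractant, fell (-0.99). Neutrophil markers were higher on the same arrays, by a list mean of 1.54, and with that mean as a covariate the chemokine call ended (adjusted p = 0.143) and the Il1b difference turned to -0.017 (adjusted p = 0.991). The list's call also ended with the early-response mean as a covariate (adjusted p = 0.826), as did the calls of Sele (0.95, adjusted p = 0.344), Cxcl2 (0.51, adjusted p = 0.881) and Il1b (0.62, adjusted p = 0.741). Interferon-stimulated genes (2 of 19 higher, 2 lower, 2 and 2 adjusted over the list alone) did not pass (adjusted p = 0.873, tested direction up, median -0.01). In them Isg15 (0.60) and Gbp3 (0.46) rose and Rsad2 (-0.87) and Ifit2 (-0.70) fell. No member of the antigen presentation list was called by limma (0 of 21, and 0 adjusted over the list alone; adjusted p = 0.218), the largest differences being 0.53 for Cd86 and 0.47 for H2-Aa.

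Few proliferation genes were called. Mki67, a marker of cycling cells, differed by 0.31 (SE 0.14, adjusted p = 0.215). Of 29 cell cycle genes 1 rose, the kinase Cdk1 (0.82), and 1 fell, the replication licensing factor Mcm3 (-0.32), also 1 and 1 adjusted over the list alone. The list passed at the preset correlation (median 0.15, adjusted p = 0.00599) and was lost at adjusted p = 0.341 with an estimated correlation and 0.0855 with fry. Mcm3 lost its call without control 3, control 4 or NICD_OE 3 (range -0.36 to -0.29). Among 12 p53 targets 0 rose and 2 fell (0 and 2 adjusted over the list alone; adjusted p = 0.449), the death receptor Fas (-0.75) and Zmat3 (-0.44). Zmat3 lost its call without control 3, control 4 or NICD_OE 6 (range -0.50 to -0.37), and the list gained one with the neutrophil marker mean as a covariate (adjusted p = 0.0401).

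**Figure D3:**
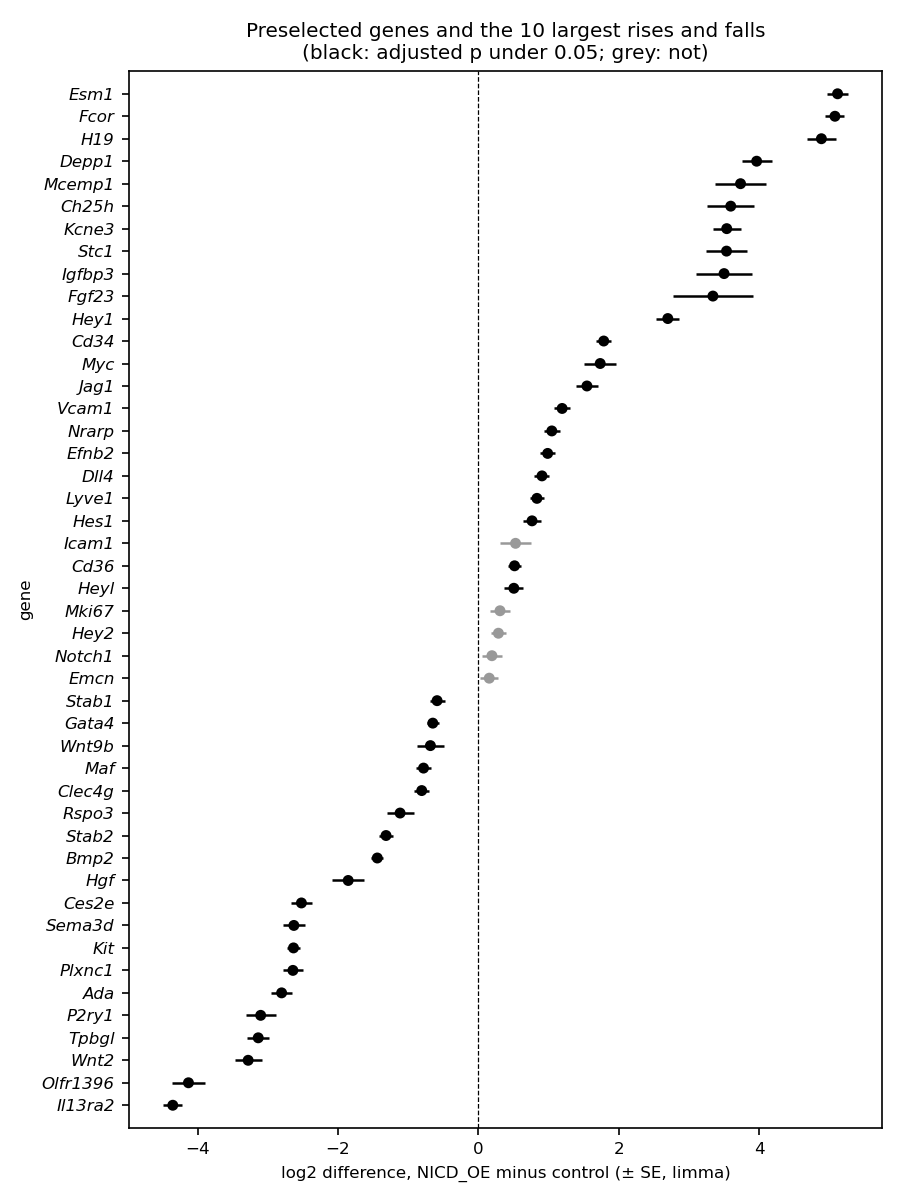
Log2 difference, NICD_OE minus control, with ± SE from limma (x axis) for the 28 preselected genes and the 10 largest rises and falls (y axis), n = 6 arrays per group; black points have an adjusted p under 0.05 and grey points do not. Esm1 (5.11) stands at the top and Il13ra2 (-4.35) at the bottom.

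The other 9 genes named for their rise had varied functions. Fcor, a corepressor of Foxo1, rose from 4.09 ± 0.15 to 9.17 ± 0.32, 33.7-fold (adjusted p = 1.25e-11), and H19, an imprinted long noncoding RNA, from 3.18 ± 0.37 to 8.06 ± 0.47 (adjusted p = 1.47e-09). Depp1 rose by 3.96, the oxysterol-making enzyme Ch25h by 3.59, the potassium channel subunit Kcne3 by 3.53, the secreted glycoprotein Stc1 by 3.53 and the myeloid membrane protein Mcemp1 by 3.73. Fgf23, a hormone of phosphate balance, rose by 3.34 with a wide spread (NICD_OE SD 1.68, adjusted p = 0.00106). It was highest on NICD_OE 5 (8.75), the array with the highest early-response mean. Fcor, Depp1, Ch25h, Kcne3, Stc1 and Igfbp3 were highest there too, but H19 was highest on NICD_OE 3 and Mcemp1 on NICD_OE 1. Il13ra2, a decoy cytokine receptor, fell from 6.47 ± 0.31 to 2.12 ± 0.14 (adjusted p = 3.03e-11), and the olfactory receptor gene Olfr1396 fell too (-4.13). Tpbgl fell by 3.14, the ADP receptor P2ry1 by -3.10, adenosine deaminase (Ada) by -2.80, the guidance cue Sema3d by -2.63 and the carboxylesterase Ces2e by -2.52. For each of these genes all 6 NICD_OE arrays lay on one side of all 6 controls, which the naming rule required. H19, Mcemp1, Stc1, Fgf23, Il13ra2, Olfr1396 and Ces2e are among the genes whose lower level cannot be separated from background.

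Early-response genes, which cell isolation can induce, were higher in NICD_OE. Of 16, 14 rose and 0 fell (16 and 0 adjusted over the list alone; median 1.39, adjusted p = 9.63e-15), a call lost at adjusted p = 0.0859 with an estimated correlation. The transcription factors Egr1 (2.23), Fos (1.95) and Junb (1.71) and the mRNA decay factor Zfp36 (1.74) rose. The list mean was 7.67 ± 0.45 in control and 8.96 ± 0.52 in NICD_OE (SD, n = 6 each; exact permutation p = 0.00433), highest on NICD_OE 5 (9.87). With this mean as a covariate 368 probe sets were higher and 288 lower, and 52 of the 135 named genes lost their call.

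Markers of several other cell types differed between the groups as well. Neutrophil and monocyte markers rose, 9 of 15 with 0 lower (10 and 0 adjusted over the list alone; median 1.27, adjusted p = 7.69e-10), lost at adjusted p = 0.0781 with an estimated correlation. Among them the granule protein Ngp rose by 3.18, Retnlg by 3.13, and the calprotectin subunits S100a8 and S100a9 from 5.61 to 8.54 and from 5.14 to 7.91. With their mean as a covariate, 334 probe sets were higher and 407 lower. Besides 38 named genes that lost their call, Il1b lost its call and turned in direction. Every measured cholangiocyte marker rose, 8 of 8 (8 adjusted over the list alone; median 1.05, adjusted p = 3.12e-10, or 0.00951 with an estimated correlation), among them Tspan8 (1.53), the keratins Krt8 (from 5.56 to 7.06) and Krt18 (1.39), and Sox9. Sox9 and Krt19 also stand in other lists. Hepatocyte markers gave 6 rises and 0 falls among 17 (12 and 1 adjusted over the list alone; median 0.94, adjusted p = 1.28e-05), lost at adjusted p = 0.265 with an estimated correlation, 0.215 with the neutrophil marker mean as a covariate and 0.0559 with fry. Tat rose by 1.76, albumin (Alb) from 9.59 ± 0.36 to 10.71 ± 0.45, transferrin (Trf) by 1.06 and Apoc3 by 0.94. Over single arrays left out Tat differed by 1.40 to 2.11 and kept its call in 4 of 12 fits, those without control 1, control 4, NICD_OE 3 or NICD_OE 6. Apoc3 differed by 0.80 to 1.08 and lost its call in 5 of 12, those without control 3, 5 or 6 or NICD_OE 1 or 2.

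Kupffer cell and stellate cell markers gave weaker calls. The Kupffer list (1 of 14 higher, Marco, 0 lower, 2 and 0 adjusted over the list alone; median 0.35, adjusted p = 0.00492) was lost at adjusted p = 0.542 with an estimated correlation, 0.267 with fry and 0.0614 without NICD_OE 1. With the hepatocyte marker mean as a covariate its direction turned to lower (adjusted p = 0.0973), and with the neutrophil marker mean, higher by 1.54 on the same arrays, its call ended (adjusted p = 0.447). In the stellate cell and fibroblast list 4 of 15 rose and 2 fell (5 and 3 adjusted over the list alone; median 0.23, adjusted p = 0.0419), lost at adjusted p = 0.609 with an estimated correlation and when control 1, 2 or 3 or NICD_OE 2 or 6 was left out (highest adjusted p = 0.160). It was also lost with fry (0.113), array weights (0.0685), the dimmest 25 or 50 percent of probe sets left out (0.0601 and 0.0942) and the early-response mean as a covariate (0.698). Its risers were the fibrillar collagens Col1a1 (2.49), Col3a1 (2.11) and Col1a2 (1.71) and the pericyte gene Rgs5 (1.09), whereas the stellate cell genes Lrat (-0.75) and Colec10 (-0.94) fell. Lymphatic markers gave 4 rises and 1 fall among 7 (4 and 1 adjusted over the list alone; median 0.83, adjusted p = 0.00418), lost at adjusted p = 0.0798 with an estimated correlation and 0.0570 with the early-response mean as a covariate, with Nts (2.47), Mmrn1 (1.46), the lymphatic regulator Prox1 (0.91) and Lyve1 higher. Mesothelial markers (2 of 7 higher, 0 lower, 2 and 0 adjusted over the list alone; median 0.14, adjusted p = 0.00799) were lost at adjusted p = 0.0913 with an estimated correlation, 0.143 with the neutrophil marker mean as a covariate and 0.0853 with the early-response mean, the 2 being Gpm6a (1.64) and Krt19 (0.84). Platelet markers (2 of 8 higher, 0 lower, 2 and 0 adjusted over the list alone; median 0.16, adjusted p = 0.0119) were lost at adjusted p = 0.0632 with an estimated correlation, 0.491 with the neutrophil marker mean as a covariate and 0.0548 with the early-response mean, with Ppbp (1.01) and Pf4 (0.56) higher.

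Lymphoid, dendritic and erythroid lists did not pass. For T and NK cell markers limma called 0 of 16 (0 adjusted over the list alone; adjusted p = 0.0599), with Gzmb at 0.68 (0.45 to 0.96 over single arrays left out, called without NICD_OE 4) and Ccl5 at 0.51 (0.25 without NICD_OE 6 to 0.94 without NICD_OE 4), and the list passed when control 1, control 6, NICD_OE 4 or NICD_OE 5 was left out, at adjusted p = 0.0485, 0.0306, 0.00326 and 0.0139. For B and plasma cell markers it called 0 of 11 (0 adjusted over the list alone; adjusted p = 0.126), with Ighm at 0.73 (called without NICD_OE 4) and Blnk at 0.55 (called without control 5 or NICD_OE 3 or 4), and the list passed without NICD_OE 4 (adjusted p = 0.0195) or NICD_OE 5 (0.0330). Dendritic cell markers gave 1 rise, the lectin Cd209a (2.22), and 2 falls, Zbtb46 (-0.99) and Clec9a (-0.91), among 10 (3 and 2 adjusted over the list alone; adjusted p = 0.580). Erythroid genes gave 0 calls among 8 (0 adjusted over the list alone; adjusted p = 0.694), with Hbb-bt at 0.65 (0.23 without NICD_OE 1 and 0.12 without NICD_OE 2, up to 0.97 without NICD_OE 6) and Hbb-bs at -0.08 (-0.22 to 0.11 over single arrays left out). The T and NK cell list also passed with the replicate number as a block (adjusted p = 0.0199) and with array weights (0.0139). With the early-response mean as a covariate the T and NK cell (adjusted p = 0.00250), B cell (3.17e-06) and antigen presentation lists (0.00783) passed. Over all probe sets 5519 had an unadjusted p under 0.05 in the same limma fit.

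**Figure D4:**
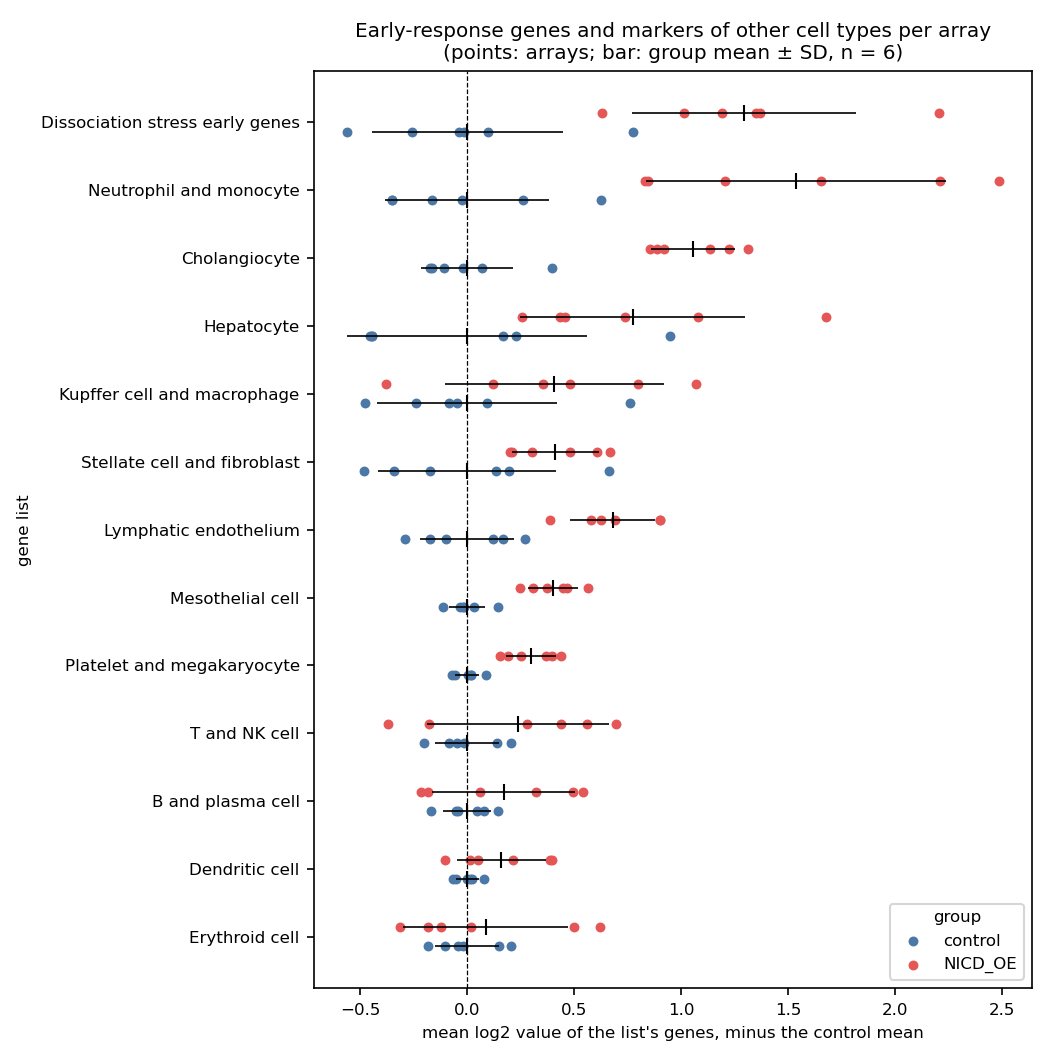
Mean log2 value over the genes of each list, minus the control mean (x axis), for early-response genes and 12 lists of markers of other cell types (y axis); points are arrays, and bars show the group mean ± SD with n = 6. NICD_OE arrays lie right of all controls for the neutrophil, cholangiocyte, lymphatic, mesothelial and platelet lists, and the groups overlap for the hepatocyte, Kupffer cell, stellate cell and lymphoid lists.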

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

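The tests of neutrophil co-isolation, endothelial share, handling and lobular zones in this part were chosen after the results were seen, whereas the regroupings of arrays and the test of neutrophil RNA as a source of early-response transcripts were not. Chance is argued against for the count of genes and for that of lists with an estimated correlation, though 100 divisions can show no less than 1 in 100. Of 100 ways to divide the 12 arrays into groups of 6, only the real one (1 of 100) gave as many as 2666 called probe sets, and the highest other gave 1. The same held for lists, 1 of 100 at the preset correlation (26 lists, highest other 24) and 1 of 100 with an estimated correlation (11 lists, highest other 0). The divisions that called 24 lists each exchanged only 1 array per side and so nearly repeat the real grouping. Those that kept 4 arrays of a group together called up to 23 lists at the preset correlation. Those that mixed the groups evenly, 3 and 3, called at most 10. A list call at the preset correlation alone therefore does not exclude chance.

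In 20 of 356 sets of 6 values, 1 array stood far from the other 5, against 17.8 that chance gives at about 1 in 20. Control 2 held 8 of them. It was lowest for Stab1 (10.50, the other controls from 10.90 to 11.10), Numb (7.40), Bmper (3.94) and the mean of Notch receptors, ligands and processing genes (6.51, the others from 6.67 to 6.74). The same array was highest for Mgp (7.12), Fabp4 (11.16), Dkk2 (3.60) and Hbb-bs (2.84). NICD_OE 5 was highest of its group for Icam1 (9.41, the others from 7.89 to 8.27), Sele (8.33, the others from 5.47 to 6.48), the mean of adhesion molecules (8.26) and the mean of chemokines, cytokines and NF-kB targets (6.99). NICD_OE 1 was highest for Numb (7.12) and for the mean of scavenger receptors (9.06), and NICD_OE 4 for Tgfb3 (5.23). Among controls, replicate 1 was highest for Hgf (8.97, the others from 7.78 to 8.13) and Trf (9.94), and replicate 5 for Zfp36 (9.29). Of the Y-linked genes, Eif2s3y was lowest of its group on NICD_OE 3 (4.81, the others from 5.49 to 5.89) and Kdm5d highest of its group on control 4 (5.13, the others from 4.61 to 4.80).

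The mean of neutrophil and monocyte markers was higher on every NICD_OE array than on any control, although CD146 selection should leave neutrophils out. S100a8 and S100a9 averaged 8.54 and 7.91 on the NICD_OE arrays. A lower share of endothelial cells, which would raise all other cell types alike, is argued against as the only source. The neutrophil marker mean rose by 1.54 and that of hepatocyte and Kupffer cell markers by 0.591, a gap of 0.949 (exact permutation p = 0.0238). The cholangiocyte marker mean, left out of that test, rose by 1.06. A lower endothelial share together with more neutrophils stays open. Within groups the neutrophil markers rose and fell together with a mean correlation of 0.438, above the 95th percentile of random lists of like level (0.061). Co-isolated neutrophils in varying amounts would give this. Markers of 1 cell type can correlate for other reasons too, so the value does not decide the source. A candidate explanation is that more neutrophils remained in the NICD_OE samples, and whether through the livers or the isolation was not tested.

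Early-response genes rose together with a within-group correlation of 0.779, against a 95th percentile of 0.085 for random lists. Genes of 1 response would correlate whatever set it off, so this value cannot decide whether handling differed between arrays, which stays open. RNA from co-isolated neutrophils cannot be told apart as a source, because the group difference of 1.29 became 1.02 with an SE of 0.521 once the neutrophil mean was a covariate, less than 2 SE from 0 and also within 2 SE of the original. An effect of Notch activation on these genes also stays open. No label gives the order or day of isolation, so handling could not be set against the groups.

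Pericentral landmarks fell while periportal and arterial ones rose. Besides Notch targets, the periportal and arterial lists share Gja5, Ltbp4, Sox17 and Clu. The listed Notch targets held by the periportal and arterial lists, 3 and 5 genes, are argued against as the only source of the rise. Without them both lists stayed higher by camera with an estimated correlation (adjusted p = 0.0157 and 0.0245). The remaining genes were not tested as Notch targets, so Notch regulation of those stays open. Fewer pericentral cells cannot be told apart from lower expression within them, because 7 of 11 landmarks fell and 2 rose, and how far each is also expressed in other cells was not measured. More arterial endothelium in the samples cannot be told apart from a change within sinusoidal cells, because the arterial genes did not move as one. Of 9 with a control mean below 6, 6 rose, and Hey2, Unc5b and Cxcl12 gave no call. Over the whole arterial list 16 of 22 rose, while Gja4 and Nrp1, both above that cutoff in control, fell. An effect of Notch activation on zonal expression within sinusoidal cells also stays open, and no test here bears on it.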

How the results depend on the processing

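The fit without control 2 and NICD_OE 4, the fits with a marker mean as a covariate and the lists without Notch targets were chosen after seeing the data, and the other alternatives were not. Across all of them the lists of Notch targets, sinusoidal identity, capillary, basement membrane, arterial, pericentral, periportal, adhesion, hypoxia, fatty acid and cholangiocyte genes kept their direction and their call. The fits with a covariate, a block or arrays left out tested lists at the preset correlation only. Median centring and quantile normalization moved no call, but the arrays already share their quantiles, so this says nothing about stability; dim genes could not be tested against background. Leaving out 1 array gave 1017 to 1323 probe sets higher and 1090 to 1647 lower, and of the 135 named genes, 122 of them called, 6 lost their call in at least 1 such fit (Heyl, Wnt9b, Tat, Apoc3, Mcm3 and Zmat3), and Gzmb, Ighm and Blnk gained one. Adjusted p then ranged from 0.00202 to 0.160 for the stellate list (not called without control 1, 2 or 3 or NICD_OE 2 or 6), 3.28e-05 to 0.0614 for Kupffer cell markers (NICD_OE 1), 0.0118 to 0.0508 for flow response (NICD_OE 5), 0.00326 to 0.272 for T and NK cells (called without control 1 or 6 or NICD_OE 4 or 5) and 0.0195 to 0.423 for B cells (called without NICD_OE 4 or 5), with fewer samples in each fit. The stellate list lost its call without the dimmest 25 percent of probe sets (adjusted p = 0.0601) or 50 percent (0.0942, with flow response at 0.101) and with array weights (0.0685, T and NK cells gaining a call at 0.0139); the cause was not tested. Requiring a log2 difference of at least 1 left 330 higher and 201 lower by construction. An estimated correlation left 9 lists higher and ended these calls, by adjusted p: scavenger 0.108, chemokines 0.0999, cell cycle 0.341, VEGF 0.0999, mesenchymal 0.119, fenestrae 0.0665, flow 0.150, early-response 0.0859, hepatocyte 0.265, Kupffer 0.542, stellate 0.609, neutrophil 0.0781, platelet 0.0632, mesothelial 0.0913 and lymphatic 0.0798. The cause was not tested list by list. Leaving Notch targets out of the other lists changed no list's call (arterial 2.38e-11, periportal 1.58e-09). With fry, angiocrine factors gained a call (0.00246) and cell cycle (0.0855), hepatocyte (0.0559), Kupffer (0.267) and stellate (0.113) lost theirs; fry compares a list with no other genes. Without control 2 and NICD_OE 4 together, stellate markers stood at 0.130, T and NK cells at 0.00375 and B cells at 0.0262, with the cause not tested.

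The groups share replicate numbers, and no label says what a number marks. Over all probe sets single numbers were not shown to pair the samples, but replicates 1 and 2 stood apart in both groups. On the third principal component (8.73% of variance) they scored 18.2 and 16.7 in control and 24.7 and 15.7 in NICD_OE. Replicates 3 to 6 scored from -12.4 to -6.47 in control and from -18.0 to -1.01 in NICD_OE. Same-numbered arrays deviated from their group means with correlations of 0.219, -0.070, -0.105, -0.088, 0.178 and 0.103, and only replicates 1 and 5 correlated best with their own number in both groups. Hepatocyte marker means went together by number, a relation chosen after seeing the data (n = 6 pairs, Pearson's r 0.961, exact permutation p = 0.00972; Spearman's rho 0.943, exact permutation p = 0.0167; r 0.972 without the 2 pairs farthest from the control median). Kupffer cell marker means also went together by rank (rho 0.943, exact permutation p = 0.0167; r 0.808, exact permutation p = 0.0542). Erythroid, mesenchymal and scavenger means did so by r only (0.883, 0.839 and 0.780, exact permutation p = 0.0347, 0.0278 and 0.0292). Of 38 lists compared in this way 0 passed adjustment (adjusted p = 0.330 and 0.317 for hepatocyte markers). NICD_OE was higher in 6 of 6 same-numbered pairs for hepatocyte markers, by 0.51 to 0.91. These markers and the third component leave a day or batch shared between the groups open. With the replicate number as a block, 1294 probe sets were higher and 1213 lower. Of the 135 named genes 3 lost their call and 1 gained one. The stellate list stood at adjusted p = 0.0622 and T and NK cells at 0.0199, and no other list changed its call (hepatocyte markers 6.64e-12).

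Covariates that differ between the groups take up part of the group difference, so calls they end are not shown to come from those cells. With the hepatocyte mean, 867 probe sets were higher and 904 lower, 11 named genes lost their call, and Kupffer markers turned lower (adjusted p = 0.0973). With the neutrophil mean, 334 were higher and 407 lower. Besides 38 named genes that lost their call, Il1b lost its call and turned to -0.017. Adjusted p became 0.143 for chemokines, 0.482 for flow response, 0.215 for hepatocyte, 0.447 for Kupffer, 0.491 for platelet and 0.143 for mesothelial markers, and p53 targets gained a call (0.0401). With the early-response mean, 368 were higher and 288 lower, and 52 of the 135 named genes lost their call. Chemokines stood at 0.826, flow response at 0.422, stellate at 0.698, platelet at 0.0548, mesothelial at 0.0853 and lymphatic at 0.0570, while antigen presentation (0.00783), T and NK cells (0.00250) and B cells (3.17e-06) gained calls. The cause was not tested in any of these fits.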

Other observations

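The lists in this part were chosen after the data were seen, from themes among the most changed genes, so their tests describe these arrays and are not independent evidence. Genes of the insulin-like growth factor axis were higher, 7 of 15 with 0 lower (adjusted p = 9.33e-09, or 8.51e-04 with an estimated correlation). Beside H19 and Igfbp3 they included Igfbp5 (3.26), the growth factor Igf2 (1.78), which shares an imprinted locus with H19, and Igf1 (0.95). Among 21 genes of natriuretic peptide signalling, cyclic GMP and potassium channels 9 rose and 3 fell (adjusted p = 1.68e-06, or 0.0189 with an estimated correlation). Both subunits of soluble guanylate cyclase, Gucy1a1 (2.05) and Gucy1b1 (2.66), rose, as did the clearance receptor Npr3 (2.67), while the guanylate cyclase receptors Npr1 (-0.92) and Npr2 (-0.52) fell. The potassium channel subunits Kcnj8 (2.99) and Abcc9 (3.26), which form a vascular ATP-sensitive channel, and Kcnj2 (3.26) rose with Kcne3. Mural cell genes gave 7 rises and 0 falls among 14 (adjusted p = 2.40e-06), lost at adjusted p = 0.0573 with an estimated correlation, with Rgs5, Anpep (1.05) and Vtn (0.94) higher and the pericyte genes Cspg4 and Higd1b at 0.16 and -0.03 without a call, both below the array median of 3.67 in control.

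Several metabolic and signalling genes fell. Of 20 genes of purine handling 10 fell and 3 rose (adjusted p = 7.08e-05), lost at adjusted p = 0.136 with an estimated correlation. With P2ry1 and Ada, the fallers included the phosphorylase Pnp2 (-2.21), the ATP-gated channels P2rx4 (-1.06) and P2rx7 (-0.97) and the nucleoside transporter Slc29a1 (-0.84), while adenosine kinase (Adk, 0.86) rose. Of 22 genes of retinoid metabolism 5 fell and 1 rose (6 and 5 adjusted over the list alone; median 0.09). The list did not pass (adjusted p = 0.647, though 8.35e-04 with fry). The retinoic acid hydroxylase Cyp26b1 (-2.08), the reductase Dhrs3 (-1.71) and the receptors Rarb (-1.65) and Rarg (-0.99) fell with Lrat. Eicosanoid genes gave 5 falls and 2 rises among 25 (adjusted p = 0.132, though 0.00158 with fry). The lipoxygenase Alox12 (-2.35), Slco2a1, the leukotriene synthase Ltc4s (-1.98), the thromboxane receptor Tbxa2r (-1.88) and the prostaglandin dehydrogenase Hpgd (-1.24) were lower. Among 23 semaphorins, plexins and neuropilins 7 fell and 3 rose (adjusted p = 0.230, though 0.00246 with fry).

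Small nucleolar RNAs had a median difference of 0.41 over 100 probe sets, with 7 higher and 0 lower, and 64 probe sets of ribosomal protein genes had a median of 0.04. For 543 microRNA probe sets the median was -0.01, with 3 higher and 9 lower. Xist lay between 2.10 and 2.39 on all 12 arrays, and the Y-linked Eif2s3y between 4.81 and 6.39.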
